A study of Homo sapiens with 6 samples.

How the data were processed

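Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in Nthy-ORI, an immortalised human cell line derived from normal thyroid follicular epithelium. Per the labels' protocols, cells were kept for 24 h in hormone-stripped medium and then received 10 nM T3 (triiodothyronine, the active thyroid hormone) or the NaOH vehicle. Nuclei of 50000 cells entered each transposition. The 6 samples form 3 groups of 2: vehicle, labelled 6 h, T3 for 6 h and T3 for 24 h. A vehicle sample at 24 h was not analysed here, so hormone and time after medium change cannot be told apart at 24 h. The labels do not say whether the 2 samples of a group came from separate cultures.

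The deposited files are 3 peak lists, 1 per group, each made by the authors from both replicates of that group. The submitters' processing notes name CASAVA 1.7, Trim Galore, Bowtie2, MACS2 and DiffBind and the build hg38, without settings or order. Whether reads were shifted for the Tn5 cut, how duplicates and mitochondrial reads were treated and whether a blacklist was applied are not given in the sources used here. The 20 columns of each list follow the layout of the IDR method, which keeps peaks whose strength ranks alike in 2 replicates and gives each an irreproducible discovery rate (IDR). The deposited score is the scaled IDR, from 540 to at most 1000, and the lists also hold the −log10 of the IDR as deposited. From these values every deposited peak had an IDR of at most 0.05. The deposited signal of a peak is the sum of its signal in the 2 replicates. Its normalisation is not stated, so signals were used only to rank and describe peaks within 1 list and never compared between lists. The columns for p-values and q-values held no values. The 2 replicate columns carry no sample name and were used as 2 unnumbered replicates of the group. The lists give no read counts, so the sequencing depth of the samples is unknown, and no value for a peak missing from a list can be had.

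Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks of 2 lists were shared when they overlapped by at least 50% of the shorter peak. The overlap code was checked against bedtools 2.31.1. As background each list was placed at random on its own chromosomes 100 times. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between cultures. Peak position was the mean of the 2 replicate summits, because the merged summit column often lay outside them. No genome sequence or transcript annotation was used here. Genes came from the RefSeq table of GRCh38.p14, the same assembly as hg38 for chromosomes 1 to 22 and X, with 19974 protein-coding genes there. That table gives gene boundaries without strand. The planned promoter class therefore became "gene end", a summit within 1 kb of either boundary of a protein-coding gene, and start and end of a gene could not be told apart. Starts of inner transcripts count as gene body. Exons and motifs were not analysed, and random gene lists were matched on gene length in 5 classes in place of promoter GC content.

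There was 1 list per group and thus no replicated value per condition, so no p-value between conditions is given. A gene list was described by its number of members with a peak and by the percentile of that number among 10000 random gene lists of the same size. In the gene-end counts a peak counts for every gene with an end within 1 kb of its summit. For counts over a locus, each peak, at a gene end or not, was assigned to the gene with the nearest protein-coding gene end within 100 kb, so there a peak counts for 1 gene only. The planned random lists for these counts were matched on the number of peaks assigned, which includes the gained peaks themselves, so their percentiles are not used. The 17 gene lists, the rule for naming genes and the alternatives, except the limit on the distance of replicate summits, were fixed before the data were examined. The rule named up to 4 genes per list by the signal of a gained peak at a gene end, a set of hormone, thyroid and remodeller genes, the 10 strongest gained and 5 strongest lost peaks at gene ends, the 5 strongest gained peaks elsewhere, and the 5 genes with most gained peaks. The same rule was applied to the comparison of both T3 lists. One gene-end peak that the rule selects there is not reported here. "Gained" means present in a T3 list with no shared vehicle peak, and "lost" the converse; both describe lists. Tested on simulated data, the overlap code found 100% of 600 planted overlaps between lists of the size of vehicle and T3 6 h. With 19974 genes, 1% of 100 unchanged lists and 100% of 100 lists of 26 genes with 13 planted hits lay at or above percentile 97.5. The simulated share of genes with a hit lay between the 10.8% of the 6 h list and the 60.8% of the 24 h list. It was also unrelated to gene length. The simulation therefore does not show how the percentiles behave at the shares of the real lists.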

Results

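Accessible regions of Nthy-ORI thyroid cells were recorded in 3 groups of 2 ATAC-seq samples: vehicle, 10 nM T3 for 6 h and 10 nM T3 for 24 h. The series asks how thyroid hormone and its receptor TRβ shape chromatin accessibility, in connection with the SWI/SNF remodelling complexes. Each group was represented by 1 list of peaks found in both of its replicates. The vehicle list held 7103 peaks, the T3 6 h list 12385 and the T3 24 h list 60661, and they covered 9.82, 15.3 and 47.6 Mb. Read depth was not part of these lists, so a region missing from a list is not shown to be closed. There is no replicate check on any difference between lists. Intervals below cover counting error only.

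The replicates of the 3 groups did not agree equally well. At 24 h the summits of the 2 replicates lay a median of 46 bp apart, against 222 bp at 6 h and 180 bp in vehicle. Across peaks, which are not independent replicates and were selected on both columns, the signals of the 2 replicates had a Spearman rho of 0.69 at 24 h, 0.05 in vehicle and -0.28 at 6 h. The share of peaks with the highest possible IDR score was 59.2% at 24 h, 18.5% at 6 h and 29.5% in vehicle. Median peak width fell from 1290 bp in vehicle and 1160 bp at 6 h to 696 bp at 24 h.

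The position of peaks relative to genes differed as well. Of the peaks on chromosomes 1 to 22 and X, 3.55% of the vehicle list (95% interval 3.13 to 4.02) lay within 1 kb of an end of a protein-coding gene. The share was 14.9% (14.3 to 15.6) at 6 h and 19.1% (18.8 to 19.5) at 24 h. Peaks placed at random gave 2.44%, 2.52% and 2.65% for the 3 lists. In the 24 h list the share rose with peak strength, from 7.68% in the weakest of 10 equal classes by signal to 39.8% in the strongest. In the vehicle list it was 4.25% in the weakest class and 0.44% in the strongest, and in the 6 h list 17.2% and 9.58%. The strongest vehicle peak, with a summed signal of 106, lay at chr17:25920032-25920407 (hg38), 1.37 Mb from the nearest protein-coding gene end, and was present in both T3 lists. The next strongest, at chr17:25074290-25074710 and chr17:25389760-25390380, lay 2.22 and 1.90 Mb from one and were in both T3 lists too. How reads mapped at these sites, for instance in repeats, was not examined, so they are not shown to be open chromatin.

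**Figure D1:**
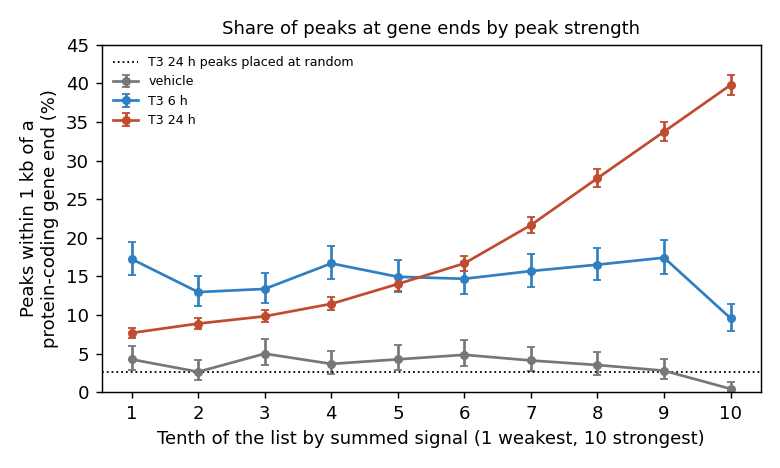
Share of peaks whose summit lies within 1 kb of a protein-coding gene end (y axis, percent), for 10 equal classes of each list ordered by summed signal (x axis, 1 weakest to 10 strongest). Points are shares with exact 95% intervals, and the dotted line is the 2.65% of randomly placed T3 24 h peaks; the 24 h share climbs to 39.8% while the vehicle share stays under 5%.

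The comparison of vehicle with T3 at 6 h, both labelled with the same time, describes how these lists differed at the early time. After 6 h of T3, 2064 protein-coding genes had a peak at a gene end that had none in vehicle, while 169 had one in vehicle and none at 6 h. The number of genes with a 6 h peak at an end, 2162, depended on the processing: it was 628 with replicate summits within 100 bp, and 1090 to 1386 with lists of equal length ranked by 1 replicate column. The gained gene-end peaks ranked highest by signal included MTR, the vitamin B12-dependent methionine synthase, HSPA4, an HSP70-family chaperone, GABPB1, a subunit of the ETS-family regulator GABP, and the gene pair ANKMY2 and BZW2. The signals of HSPA4, GABPB1 and ANKMY2/BZW2 were 16.4, 16.6 and 16.7, and MTR stood highest by summed signal, at percentile 96.7 of the 6 h list. It led in neither replicate alone: PCDHB5 stood highest of these peaks in the first replicate column (8.04, MTR 5.57) and GABPB1 in the second (12.9, MTR 12.4). SUCO, METTL2B, SPHKAP, PCDHB5, TAF11L3 and the pair KIAA1328 and TPGS2 completed the 10 strongest, between 15.9 and 17.6. For GABPB1, ANKMY2/BZW2 and TAF11L3 the 2 replicate summits lay over 1 kb apart, at 1111, 1366 and 1221 bp. The strongest gained peaks elsewhere were in SLC5A4 and MLPH, and in intergenic DNA 56060 bp from CIROZ and over 1 Mb from OR11H1 and LINC02798, with a lowest signal of 18.4. Read mapping at these peaks was not examined. GLI3, a transcription factor of Hedgehog signalling, had the most gained peaks assigned to it as the nearest gene end within 100 kb, 8, followed by POTEG with 7 and EML6, COBL and AUTS2 with 6 each. These counts were not set against a background for gene length or local peak density.

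Of the 7103 vehicle peaks, 2356 (33.2%, interval 32.1 to 34.3) were shared with the 6 h list, against a mean of 102 after random placement, so that 4747 were lost. Sharing was most frequent among strong peaks. Of the strongest of 10 equal classes by vehicle signal, on chromosomes 1 to 22 and X, 88.7% were shared, and of the weakest 15.7%. Only 0.44% of that strongest class lay at gene ends, and how its reads mapped was not examined. Of the 12385 peaks at 6 h, 2373 (19.2%, 18.5 to 19.9) were shared with vehicle and 10012 were gained. Gained 6 h peaks lay at gene ends in 17.3% of cases (16.6 to 18.1) and shared ones in 3.98% (3.2 to 4.88), while lost vehicle peaks did in 3.34% (2.84 to 3.90). The 5 strongest lost gene-end peaks were those of TGM6, IMMT, ZNF736, RNF34 and ICE1, with vehicle signals between 12.7 and 13.5. Those of IMMT, RNF34 and ICE1 were shared with the 24 h list and thus missing at 6 h only, while those of TGM6 and ZNF736 were absent at 24 h too. Gained 6 h peaks ranked at a median percentile of 44.6 of their list by signal, and shared peaks at 79.1. With an IDR of at most 0.01, 2837 peaks were gained and 1880 lost.

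The comparison of vehicle with T3 at 24 h cannot tell hormone from time, because the vehicle is labelled 6 h. The lists also differed in replicate agreement, so their differences are not shown to be a hormone response. At 24 h, 11918 of 19974 protein-coding genes had a peak at a gene end and none in vehicle, and 44 showed the converse. Genes with a 24 h peak at an end numbered 12141, but 3312 with lists of equal length (3197 to 3286 ranked by 1 replicate column). The 10 strongest gained gene-end peaks were at RALGAPA2, a subunit of a Ral GTPase-activating complex, POT1, which protects telomere ends, the pair DNAJB9 and THAP5, HEMK2, PRPS1, a synthetase of the nucleotide precursor PRPP, the pair C12orf60 and WBP11, BPGM of red-cell glycolysis, UTP3, the pair ENTPD1 and TCTN3, and ZNF337. Their summed signals ran from 43.7 to 48.1, at or above percentile 99.8 of the 24 h list, and their replicate summits lay 2 to 252 bp apart. The strongest gained peaks elsewhere had signals of 59.2 to 97.9 and lay inside PDE3A, TMPRSS15 and MYOM2, 48733 bp outside SLF1 within another gene, and 506686 bp from TPTE. Those near TPTE and SLF1 and in PDE3A were only 158, 157 and 144 bp wide, against a list median of 696 bp. Those in TMPRSS15 and MYOM2 were 442 and 804 bp wide. How reads mapped at these sites was not examined. EGFR, the epidermal growth factor receptor, had the most gained peaks assigned to it, 27 against 1 vehicle peak. CRIM1 and PRKCH followed with 24 each, ZMIZ1 with 23 and GLI2 with 21. These counts, too, were not set against a background for gene length or local peak density.

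At the level of peaks, 2390 vehicle peaks (33.6%, interval 32.5 to 34.8) were shared with the 24 h list, against 266 after random placement, and 4713 were lost. Of the strongest of 10 equal classes by vehicle signal, on chromosomes 1 to 22 and X, 77.1% were shared, and of the weakest 22.1%. Of the 24 h peaks, 2455 (4.05%, 3.89 to 4.21) were shared and 58206 gained. Gained 24 h peaks lay at gene ends in 19.6% of cases (19.3 to 19.9) and lost vehicle peaks in 1.44% (1.12 to 1.83), below the 2.37% of random placement. That share was 2.59% (2.22 to 3.01) with lists of equal length, no longer below it. The 5 strongest lost gene-end peaks were at TGM6, TDRD1, ZNF736, PCDHB4 and PCDHA8, with vehicle signals of 12.2 to 13.5. Gained peaks had a median rank percentile of 49.9 in the 24 h list. The similar shares of vehicle peaks found at 6 h and 24 h rest on the longer 24 h list. With every list limited to its 7103 strongest peaks, 94.9% of vehicle peaks (94.3 to 95.4) were absent at 24 h and 73.5% (72.5 to 74.6) at 6 h. In those lists 6740 of the 24 h peaks were gained, and 39.9% of these lay at gene ends.

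**Figure D2:**
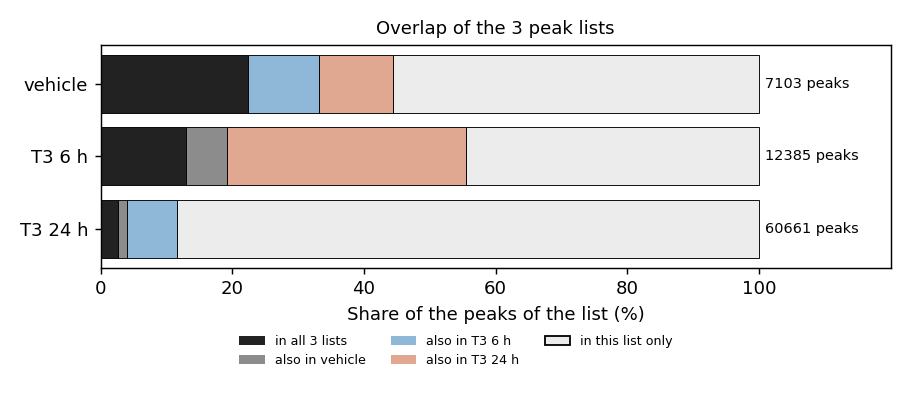
Share of the peaks of each list (x axis, percent) found in all 3 lists, in 1 other list or in that list only, with the number of peaks beside each bar. Peaks in this list only make up 55.6% of the vehicle list, 44.5% of the T3 6 h list and 88.4% of the T3 24 h list.

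The comparison of 6 h with 24 h of T3 sets the lists of both treatment times side by side. It has no vehicle at 24 h, and replicate agreement was unequal. In the full lists, most genes with a 6 h peak at an end also had one at 24 h: of 2162 such genes, 2053 (interval 94.0% to 95.8%) did, where 1314 were expected for independent lists. Away from gene ends, 41.3% (40.3 to 42.2) of 10306 peaks at 6 h were shared with 24 h, against 92.6% (91.3 to 93.8) of 1806 peaks at gene ends. In all, 6107 of the 12385 peaks at 6 h (49.3%, 48.4 to 50.2) were shared and 6278 were not, and 54467 peaks at 24 h were not in the 6 h list. Among lists of equal length, 84.3% of the 6 h peaks (83.4 to 85.1) were absent at 24 h, so the overlap of the full lists depends on their length. The 24 h peaks absent from vehicle but shared with 6 h numbered 4561, ranked at a median percentile of 79.5 of the 24 h list and lay at gene ends in 35.4% of cases (34.0 to 36.8).

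The strongest gene-end peaks at 24 h with no 6 h counterpart included those at POT1, ENTPD1/TCTN3, PIKFYVE, a lipid kinase of endosomes, ASDURF/ASNSD1, RAB2B/TOX4, CEP120, a centriole protein, SCIN, EXOC4 and TMBIM6, with signals of 41.7 to 46.5. At 6 h the strongest with no 24 h counterpart were at PCDHB5, KRTAP24-1, PCDHA6, TGM3 and NCK2, with signals of 12.9 to 17.6. The 6 h list changed with a stricter IDR: 1863 peaks with an IDR of at most 0.01 were absent at 24 h. Only 29.4% of all 6 h peaks had replicate summits within 100 bp, and among 6 h peaks found in neither other list the share was 21.0%.

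Among 26 thyroid hormone response genes, 0 had a vehicle peak at a gene end, 1 had a 6 h peak and 8 a 24 h peak, where random lists of matched length had a median of 16 at 24 h (percentile 0.13). HIF1A, the hypoxia-response factor, was the gene with peaks at both times, with signals of 12.1 in the 6 h list and 26.1 in the 24 h list. PPARGC1A, a coactivator of mitochondrial biogenesis, KLF9, an early thyroid hormone target, and ME1, the cytosolic malic enzyme, had 24 h peaks with signals of 19.4, 18.6 and 17.8. The KLF9 peak lay at chr9:70412813-70414509 (hg38), at the higher-coordinate end of the gene, with replicate summits 655 bp apart. HR and DIO1, textbook targets of the hormone, had no gene-end peak in any list, and 0 peaks of any list were assigned to DIO1 as the nearest gene. Several listed genes act in other tissues, among them TSHB, MYH6 and CYP7A1, and had none either. With summits within 100 bp, 5 response genes had a 24 h peak and 1 a 6 h peak. Cut to equal length, the lists held 1 response gene with a 24 h peak and 1 with a 6 h peak, so no rise with time was left. The response genes were the nearest gene of 72 gained peaks at 24 h and 10 at 6 h.

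Of 21 genes of the hormone signalling machinery, 0 had a gene-end peak in vehicle or at 6 h and 11 had one at 24 h (random median 14, percentile 9.78). NCOA3, a nuclear receptor coactivator, HDAC3, the histone deacetylase of the corepressor complex, MED1, a Mediator subunit, and SLC16A10, a transporter of thyroid hormone, had 24 h peaks, the first 3 with signals of 26.7, 21.2 and 16.6. The receptor genes THRA and THRB had no gene-end peak in any list, although 7 peaks at 24 h lay nearest to THRB within 100 kb. The genes of this list were the nearest gene of 88 gained peaks at 24 h. Of 18 thyroid differentiation genes, 9 had a 24 h peak (random median 11, percentile 16.2), 1 a 6 h peak and 0 a vehicle peak. DUOXA1 and DUOXA2 were both counted from the same 24 h peak. PAX8, a transcription factor of the follicular lineage, had gene-end peaks at both times, at chr2:113277744-113279065 at 6 h and chr2:113277955-113279349 at 24 h. TSHR, the thyrotropin receptor, SLC26A4, the anion exchanger pendrin, and the transcription factors HHEX and GLIS3 had 24 h peaks, with signals of 24.2 at TSHR, 19.3 at HHEX and 17.7 at GLIS3. The TSHR peak lay at chr14:80954767-80955294. The replicate summits of the 6 h PAX8 peak lay 494 bp apart, and with summits within 100 bp 0 genes of this group had a 6 h peak and 6 a 24 h peak. In lists of equal length, 1 gene of this group had a 24 h peak and 1 a 6 h peak, or 0 at 6 h when ranked by the second replicate column. TG, the thyroglobulin gene, had none at a gene end in any list and was the nearest gene of 3 peaks at 24 h, 2 at 6 h and 0 in vehicle.

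**Figure D3:**
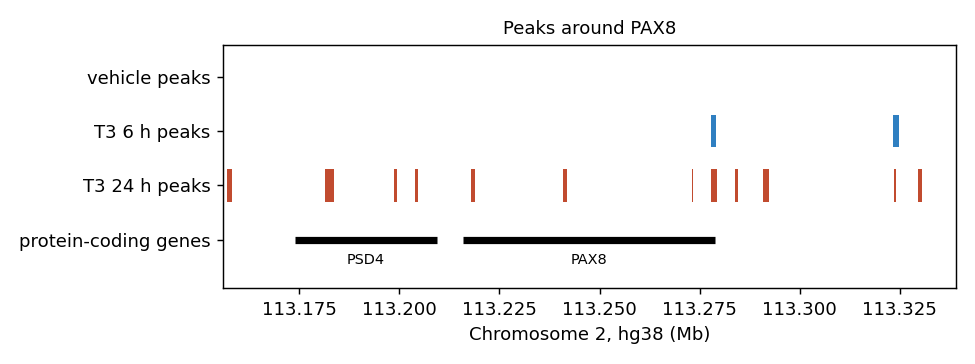
Peaks of the 3 lists (coloured boxes, drawn to scale) and protein-coding genes (black bars) around PAX8, with position on chromosome 2 in Mb (hg38) on the x axis. The window of 60 kb on either side of the gene holds 0 vehicle peaks, 2 T3 6 h peaks and 12 T3 24 h peaks.

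SWI/SNF subunit genes had 24 h gene-end peaks in 21 of 27 cases (random median 18, percentile 89.4), 6 h peaks in 4 and vehicle peaks in 0. ACTL6A, an actin-related subunit, DPF3, SMARCC1, a core scaffold, and SS18 had 24 h signals of 33.5, 26.9, 24.1 and 21.7. The ATPase gene SMARCA4 and ARID1A, the subunit that defines the canonical BAF complex, had 24 h peaks of 17.8 and 11.7 and none in the other lists. At 6 h the members with a peak were ACTL6A, SMARCE1, SS18 and BCL7B, the last at the opposite end of the gene from its 24 h peak. The replicate summits of these 6 h peaks lay 814, 154, 819 and 363 bp apart, and with summits limited to 100 bp apart 0 members had a 6 h peak. With lists of equal length, 3 members had a 24 h peak and 1 a 6 h peak, and ranked by the second replicate column 2 and 3, so the order of the times was not kept. Among 20 AP-1 and immediate early genes, 13 had a 24 h peak (random median 10, percentile 89.3), 2 a 6 h peak and 0 a vehicle peak. The strongest at 24 h were JUN, JUND (21.7), DUSP6 (21.2), a phosphatase of ERK, and MYC (17.8), while EGR1 and DUSP6 were the members with 6 h peaks. The replicate summits of the EGR1 and DUSP6 peaks at 6 h lay 265 and 200 bp apart, over the limit of 100 bp.

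Housekeeping and cell cycle genes had the most complete coverage of the fixed lists at 24 h. Of 25 cell cycle genes, 23 had a 24 h gene-end peak (random median 15, percentile 99.97) and 7 a 6 h peak (random median 2, percentile 99.2), and 0 had a vehicle peak. CDK1, the mitotic kinase, AURKA, CCNB1 and MCM3, a subunit of the replicative helicase, had 24 h signals of 39.6, 38.4, 36.1 and 35.5. Of 21 mitochondrial genes, 18 had 24 h peaks (percentile 98.7), 3 had 6 h peaks and 0 vehicle peaks, with signals of 43.5 at ATP5F1B, 42.0 at CYCS, 32.2 at HADHA and 27.4 at TFAM. Of 21 glycolysis genes, 17 had 24 h peaks (percentile 97.1), led among gained ones by PGK1 (33.1), PGAM1 (24.1), PFKM (21.7) and GPI (19.1), with 0 at 6 h and 1 in vehicle, LDHB. Housekeeping genes, which are transcribed in most cells, had 24 h peaks in 21 of 22 cases (random median 13, percentile 99.99), 6 h peaks in 3 and a vehicle peak in 1, RAB7A. ACTB, TBP, HPRT1 and B2M had a 24 h peak and none in vehicle or at 6 h. EMC7, RPLP0, VPS29 and PSMB2 had 24 h signals of 35.6, 31.2, 31.2 and 28.1. With lists of equal length, 12 cell cycle and 6 housekeeping genes had a 24 h peak, and 4 and 1 a 6 h peak. With summits within 100 bp, 4 cell cycle and 0 housekeeping genes had a 6 h peak. The low number of vehicle peaks thus held for housekeeping genes too, a measured fact to set beside every gained count above.

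**Figure D4:**
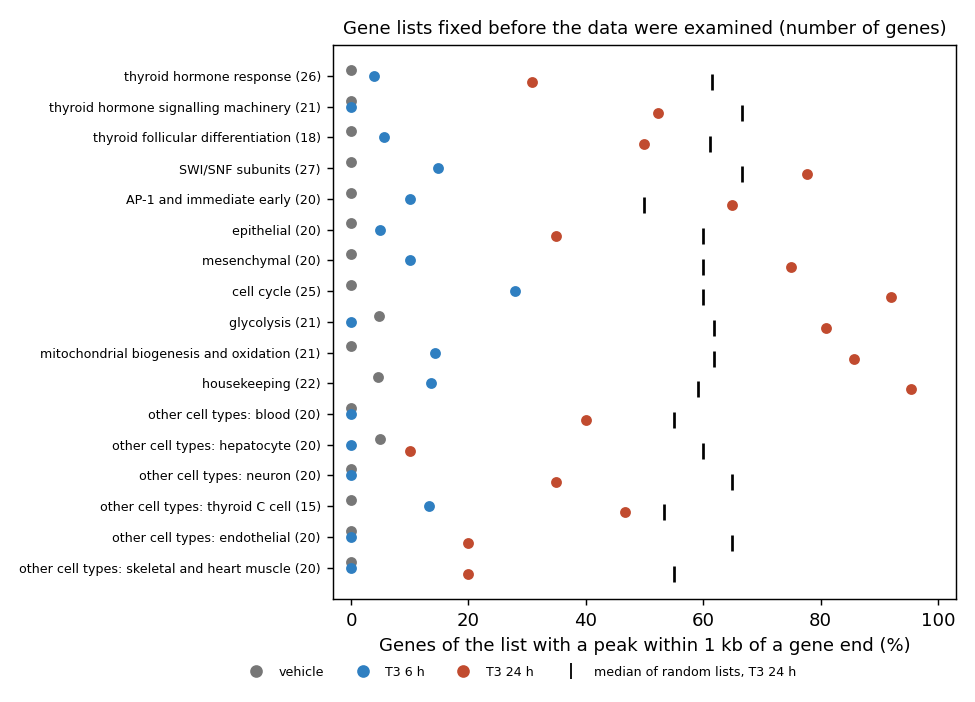
Percent of the genes of each fixed list (rows, number of genes in brackets) with a peak within 1 kb of a gene end in the vehicle, T3 6 h and T3 24 h lists, with black ticks for the median of 10000 random lists matched on gene length in the T3 24 h list. Housekeeping and cell cycle genes lie above their ticks at 24 h, and vehicle values are at most 1 gene in every list. Lists below their ticks include hormone response genes, epithelial genes and markers of hepatocytes, neurons, endothelium and muscle.

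Of 20 epithelial genes, 7 had a 24 h peak (random median 12, percentile 0.67), with signals of 15.9 at OCLN and 15.6 at CLDN1, and CDH1 and ESRP1 had none. KRT8 and KRT18 were both counted from the same peak of signal 20.3, where their ends overlap. Of 20 mesenchymal genes, 15 had one (random median 12, percentile 88.7), with 25.5 at SNAI2, 22.6 at VIM, 19.4 at ACTA2 and 18.7 at ZEB1. At 6 h 1 epithelial and 2 mesenchymal genes had a peak, and in vehicle 0 of either. Among markers of cell types other than follicular cells, 4 lists had 24 h peaks in fewer genes than random lists: 2 of 20 hepatocyte genes (percentile 0), 4 of 20 endothelial genes (0.005), 4 of 20 muscle genes (0.08) and 7 of 20 neuronal genes (0.48). Blood genes, with 8 of 20 (percentile 8.46), and C cell genes, with 7 of 15 (27.7), lay within the central 95% of random lists. The gene with the strongest 24 h peak in each list was SYT1 of neurons (31.7), CD8A of blood (31.6), CHGB of C cells (24.4), TF of hepatocytes (21.7), KDR of endothelium (18.2) and RYR2 of muscle (11.5). At 6 h these 6 lists had peaks at CHGB and ISL1 of the C cell list only, and vehicle had 1, at APOC3 of the hepatocyte list.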

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

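The limit to peaks with replicate summits within 100 bp was chosen after the data were seen; the other settings were set before. No paired analysis was possible because each list pools both replicates of its group and its replicate columns carry no number. A stricter q-value and the motif comparisons were not run. Membership in a list rests on both replicates, so leaving one out could only be done by ranking peaks on 1 replicate column. Counts of unshared peaks stayed within 1.5 times of their values with an overlap of 1 bp, with an overlap of 50% of both peaks and on chromosomes 1 to 22 and X. Unknown depth limits every count, and the cause of a change was not tested except where a setting keeps fewer peaks by construction.

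With an IDR of at most 0.01, 3088 vehicle and 4048 T3 6 h peaks were left. Of these, 1880 vehicle peaks were absent at 6 h and 1920 at 24 h, and 2837 peaks of the 6 h list were absent from vehicle and 1863 from 24 h. With summits within 100 bp, 2723 vehicle and 3637 T3 6 h peaks were left, with 1894 vehicle peaks absent at 6 h, 1854 absent at 24 h, and 2808 and 1999 of the 6 h peaks absent from vehicle and 24 h. The vehicle share at gene ends was then 2.25%, that of gained 6 h peaks 18.8%, and 64 genes had a vehicle and 628 a 6 h peak at an end. At 6 h, the genes with a peak then fell to 0 of the SWI/SNF, housekeeping and thyroid differentiation lists and 4 of the cell cycle list, in vehicle to 0 of the housekeeping list, and at 24 h to 5 of the hormone response list.

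With lists of equal length, 6740 of the 24 h peaks were absent from vehicle and 5989 from 6 h, and 5218 of the 6 h peaks were absent from vehicle. Gene-end shares were 39.2% at 24 h, 39.9% of gained 24 h peaks, 18.7% of gained 6 h peaks and 2.59% of vehicle peaks absent at 24 h, and 3312 genes had a 24 h and 1251 a 6 h peak at an end. Ranked on 1 replicate column, those values ranged from 6700 to 6755, 5654 to 6271 and 5297 to 5408 peaks, from 38.0% to 38.8%, 38.6% to 39.8%, 15.97% to 20.6% and 2.59% to 2.65%, and from 3197 to 3286 and 1090 to 1386 genes. The gene-end share of the whole 6 h list then ran from 13.2% to 16.5%. The median rank percentile ran from 45.4 to 46.2 for gained 6 h peaks and from 41.8 to 42.2 for vehicle peaks lost at 6 h.

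With a gene end window of 2.5 kb the shares were 5.56% in vehicle, 18.1% at 6 h, 24.0% at 24 h, 20.8% and 24.6% of peaks gained at 6 h and 24 h and 3.34% of vehicle peaks absent at 24 h, and 431 genes had a vehicle peak. Cell cycle genes with a vehicle peak then numbered 2, against 0 with 1 kb.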

Other observations

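The tests on housekeeping genes, hormone response genes and replicate summits were chosen before the values they measure were seen, although the low vehicle share at gene ends was known by then. The tests on list length, on lost gene-end peaks and on chromosomes, the gene families, and the comparisons of summits with vehicle peaks shared with 1 T3 list alone were chosen after. The comparison of the housekeeping share with that of all genes was also added after. By the rule set with it, the outcome of the housekeeping test changed from weaker enrichment to undecided. That outcome is kept below for genes outside the housekeeping list. Gene families outside the fixed lists showed the same order of the 3 lists. Of 80 cytosolic ribosomal protein genes, 77 had a 24 h peak at a gene end (random median 39), 13 a 6 h peak (random median 6, percentile 99.6) and 0 a vehicle peak. Mitochondrial ribosomal protein genes had 71, 13 and 2 of 77. Zinc finger genes named ZNF had 385 of 517 at 24 h (random median 327), 48 at 6 h (random median 61, percentile 3.49) and 10 in vehicle. Olfactory receptor genes, which are silent in most tissues, had 25 of 392 at 24 h (random median 192), 8 at 6 h (random median 29) and 3 in vehicle.

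The clustered protocadherin genes did not all follow that order. The alpha cluster had 1 of 13 members in vehicle, 2 at 6 h and 1 at 24 h, the gamma cluster 1, 2 and 7 of 22, and the beta cluster 2 of 16 members in each of the 3 lists, with a vehicle percentile of 99.1 and a 24 h percentile of 0.33. Of the 146 genes with a vehicle or 6 h peak and none at 24 h at a gene end, 8 were protocadherins of the 3 clusters, among them PCDHA8, PCDHB4 and PCDHB5, and 6 were olfactory receptors. Reads shared between paralogs were not examined.

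The first pattern is that gene ends held few vehicle peaks and many T3 peaks. List length alone is argued against, since the 24 h list limited to 7103 peaks still had 39.2% at gene ends against 3.55% in vehicle. A 24 h gain at gene ends concentrated on the listed hormone response genes is argued against, since their 8 gained genes lay at percentile 0.29 of random lists. This covers the list as fixed and gene ends only. Several of its genes act in other tissues, and marker lists of endothelium and muscle lay as low, at percentiles 0.01 and 0.085. Response genes active in thyroid cells and distal regions were not tested separately. Outside the housekeeping genes, weaker enrichment of open chromatin over background in the vehicle libraries cannot be told apart from a wide opening of promoters by T3. At 24 h an opening with time in culture stays possible too, whereas vehicle and T3 6 h carry the same labelled time. Of 21 housekeeping genes with a 24 h gene-end peak, 4.76% (interval 0.12 to 23.8) also had a vehicle peak. This low share met the prediction written beforehand for weaker enrichment. Without weaker enrichment, most of these genes, a class transcribed in most cells, were predicted to have a vehicle peak. For these 21 genes the share therefore argues against an opening without weaker enrichment, although their transcription was not measured here. In a comparison added afterwards, only 1.84% of all 12141 genes with a 24 h gene-end peak also had a vehicle peak. That share lies within the interval of the housekeeping genes, so it cannot decide between the explanations for the other genes. Reads per sample, which would decide, were not used here.

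The second pattern is that 3949 of 7103 vehicle peaks (55.6%) had no counterpart in either T3 list. Of these, 1.56% (1.19 to 2.0) lay at gene ends, below the 3.55% (3.13 to 4.02) of the whole vehicle list. This cannot decide on closing of regulatory regions at gene ends, because the 24 h list had peaks at ends of 60.8% of genes. Vehicle peaks at gene ends were shared with 24 h in 72.7% of cases, and those elsewhere in 31.2%. Of vehicle peaks absent at 6 h, 3.34% (2.84 to 3.90) lay at gene ends, close to the whole list. Of vehicle peaks absent at 24 h, 2.59% (2.22 to 3.01) lay there with lists of equal length. Background in regions of high read density cannot be told apart from closing of distal regions. Replicate summits of vehicle-only peaks lay a median of 220 bp apart (bootstrap interval 209 to 230). This exceeded the 48 bp of vehicle peaks in both T3 lists and the 118 bp (97.0 to 140) of those shared with 6 h alone. Background would give such a difference. Vehicle peaks shared with 24 h alone lay 224 bp apart (193 to 249), so wide summit distances are not found in the unshared peaks alone. These sets also differed in strength, with median rank percentiles of 39.3, 80.6, 64.1 and 44.2 in the order given. They were not matched on strength, so the distances cannot decide.

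The third pattern is an uneven spread over chromosomes. Vehicle-only peaks numbered 3.49 per Mb on chromosome 20 and 2.5 on chromosome 7, against 0.37 on X and 0.40 on chromosome 8. Chromosomes with many vehicle-only peaks away from gene ends also had many such 24 h-only peaks, with a Spearman rho of 0.83 over 23 chromosomes per gene (r = 0.81, permutation p = 0.0001 for both, the smallest these permutations give, and 0.0005 after Benjamini-Hochberg adjustment over 5 relations); r was 0.86 without the 2 extreme chromosomes. Per Mb, which removes the shared division by genes, rho was 0.58 (permutation p = 0.0051, adjusted 0.013) and r 0.68 (permutation p = 0.0007, adjusted 0.0017), with r 0.54 without 2 chromosomes. Copy number or read density of whole chromosomes may account for this, but unequal distal openness would give the same relation and stays open; for 24 h-only gene-end peaks per Mb rho was 0.09 and r -0.06 (permutation p = 0.68 and 0.77, both adjusted as above to 0.68 and 0.85).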
